A study of Mus musculus with 8 samples.

How the data were processed

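Small RNA from mouse sperm was sequenced in 8 libraries, 4 per group. Per the labels, RNA was extracted with guanidinium thiocyanate and tris(2-carboxyethyl)phosphine, a reducing agent that opens the compact sperm head, and only the first read of each pair was used. Adapters were trimmed with cutadapt, per the submitters' processing notes, which give no version. The deposited values are counts per annotated feature, whole numbers with no normalization applied. The aligner, genome build, annotation and the rule for reads that match several places are not given in the sources used here, so features carry the table's own names and no coordinates are printed. Rows of near-identical repeat and tRNA copies carry near-identical counts, and their values are uncertain for any single copy. Each row belongs to 1 of 8 classes, and the table has no row for unannotated reads. In the deposited counts 51 features were at 0 in 1 to 4 libraries where the other libraries and a library of the same group predict 50 or more counts. The second condition was added after the values were seen, to keep out loci at 0 across a group.

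Groups were taken from the treatment label, and table columns were matched to samples by title. The replicate numbers are in accession order and pair nothing. The comparison was EtOH-Cessation against Control-Cessation. Features were kept with the filterByExpr defaults of edgeR 4.0.16 (minimum count 10, minimum total 15), scaled by the trimmed mean of M values and tested with the quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg adjustment over all 10234 features and a threshold of 0.05. Log2 fold changes are EtOH over control. CPM of single features use the scaled library sizes, and sums over a gene or list use the library totals. Class shares were compared by an exact permutation test over the 70 splits of the libraries, adjusted over the 8 classes. Lists were tested with fry in limma 3.58.1 on voom values, adjusted over the 45 lists with at least 2 tested members, which asks whether members move on balance in 1 direction and does not compare a list with other features. Intervals and floors cover counting error only, since the labels name no molecular tags.

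The tests, lists, alternatives and the rule for named features were fixed before the data were examined. The rule took up to 8 features per direction with the lowest p among those past the threshold, 4 miRNAs per direction with the lowest p, the 5 most abundant miRNAs and tRNA features, and up to 4 members with the lowest p in each list described. After the values were seen, the lists described by member were limited to 25 with a fry p below 0.05, a member past the threshold adjusted over the list alone, or epithelial miRNAs, and the gene sums of the messenger RNA lists, and the genes named from them, were added. The features named under other observations and the exon of Prps2 were also chosen after their values were seen, as was a list of 17 general epithelial genes. The lists for 5S and 18S ribosomal RNA had no tested member, and those for selenocysteine tRNA and red blood cell transcripts had 1, so these were not tested. No feature matched the list of mitochondrial tRNA and ribosomal RNA.

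Alternatives were size factors by median of ratios, library size alone, DESeq2 1.42.0, limma voom with quality weights, no filter, a mean count of at least 10, the total count as a covariate, each library left out, the EtOH libraries of either identifier form alone, fits within miRNAs and within tRNA features, centred log ratios of class shares, and camera with an estimated correlation. Added after the data were seen were fits without features with isolated zeros, scaling to piRNA cluster totals, repeat copies and exons summed, log2 ratios of each class to piRNA clusters, and an adjusted p of 0.1. The steps were tested on simulated data for this comparison, with 200 of 10234 features changed. At the estimated dispersion, 2%, 36%, 94% and 98% of features changed 2-, 4-, 8- and 16-fold were recovered, with 9 false calls among 124.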

Results

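Small RNA libraries were made from sperm of C57BL/6J mice in 2 groups, 4 libraries labelled Control-Cessation and 4 labelled EtOH-Cessation. The series title places the samples after a period without alcohol, so the comparison asks whether the sperm small RNA pool of alcohol-treated animals still differed from that of controls once treatment had stopped. The labels call every sample mature sperm, while the design text of the series speaks of the caput, the first part of the epididymis, the duct in which sperm mature. Summed counts per library were 4356786, 4210785, 4341914 and 4768713 for control replicates 1 to 4, and 6648798, 3116421, 6805989 and 5701404 for EtOH replicates 1 to 4. On the first principal component, which carried 55.3% of the variance, EtOH replicate 2 lay at 132 and the other 7 libraries between -64.9 and 39. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples.

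MicroRNAs made up a smaller part of the EtOH libraries. They held 20.2% ± 5.06 (SD, n = 4) of the counts in controls and 8.44% ± 1.71 (SD, n = 4) in the EtOH libraries, and the lowest control, at 16.8%, lay above the highest EtOH library, at 10.2%. Fragments of annotated exons went the other way, from 7.45% ± 0.283 (SD, n = 4) to 15.1% ± 10.3 (SD, n = 4), with 30.5% in EtOH replicate 2 and 9.08% to 10.4% in the other EtOH libraries. Each of these differences had a two-sided exact permutation p of 0.02857, the smallest that 4 libraries against 4 allow, and an adjusted p of 0.1143 over the 8 classes, so neither passed the correction. Structural RNA, which includes transfer RNA (tRNA) fragments, held 34.4% ± 2.42 and 38.5% ± 11.6 (SD, n = 4 each), and piRNA clusters, the sources of the germ-line piwi-interacting RNAs, 20.9% ± 4.63 and 21.9% ± 10.1 (SD, n = 4 each), differences within the spread between libraries (exact permutation p = 0.7143 and 0.8286). Introns held 7.35% ± 0.491 and 7.29% ± 0.772, antisense repeats 4.80% ± 0.783 and 4.51% ± 1.64, sense repeats 4.70% ± 0.472 and 4.24% ± 0.546, and miRNA hairpins 0.121% ± 0.0292 and 0.0776% ± 0.0140 (SD, n = 4 each), with exact permutation p of 0.8857, 0.7429, 0.2286 and 0.05714. Without EtOH replicate 2 the exon difference was 2.48 percentage points, against 7.63 with it.

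**Figure D1:**
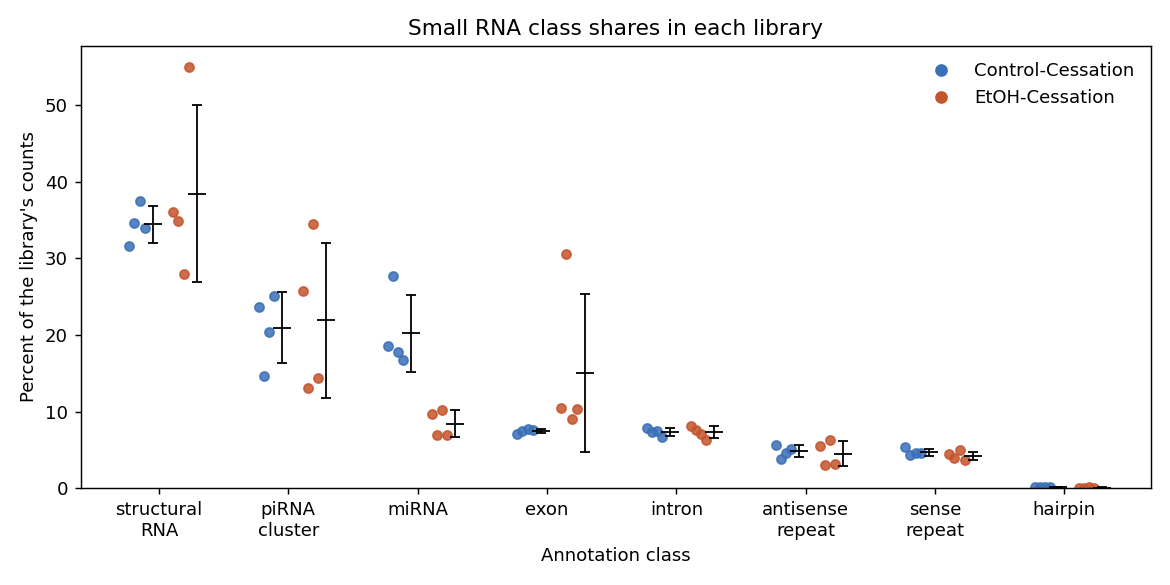
Percent of each library's counts (vertical axis) in each annotation class (horizontal axis), with 1 point per library (blue, Control-Cessation; orange, EtOH-Cessation) and a black bar for the mean ± SD of 4 libraries. The control miRNA shares all lie above the EtOH shares, and the exon share of EtOH replicate 2, at 30.5%, stands apart.

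A small set of single loci passed the adjusted threshold. Of 10234 features tested, 5 rose and 14 fell in the EtOH libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The 5 that rose were the precursor mir-196a-1, counted both as a miRNA and as a hairpin, a copy of the L2b repeat (L2b_copy13425), a copy of the endogenous retrovirus RLTR4_MM-int (RLTR4_MM-int_copy187) and an exon of 1810037I17Rik (1810037I17Rik:NM_024461.2:exon_1). Under its miRNA name, mir-196a-1 had 202 counts over the 4 EtOH libraries and 2 over the controls, a ratio of 80.2 with an exact 95% interval of 21.9 to 666 that covers counting error only (adjusted p = 0.00493). The mature product, miR-196a-5p, had isolated zeros and was not higher, with counts of 180, 0, 140 and 0 in the controls and 0, 36, 140 and 45 in the EtOH libraries (adjusted p = 0.68). Among the 14 that fell, an intron of Gpc5 (Gpc5:NM_175500.4:intron_6), a gene for a cell-surface heparan sulfate proteoglycan, had 560 ± 532 CPM (counts scaled to a common library total) in controls and 7.59 ± 4.26 in the EtOH libraries (SD, n = 4 each; log2 fold change -6.19, SE 0.89, adjusted p = 0.0113). Without control replicate 1 its control mean was 356 ± 420 CPM (SD, n = 3). A copy of the L1ME3A repeat (L1ME3A_copy920) had 65.8 ± 19.5 and 0.469 ± 0.265 CPM (SD, n = 4 each; adjusted p = 0.000106). An intron of Trim67 (Trim67:NM_198632.2:intron_4) had 202 counts over the controls and 0 over the EtOH libraries, at least 68.4-fold lower by the exact 95% counting interval. The repeat copy RMER5_copy3499 had 66 and 0, at least 21.9-fold lower. The introns Hs1bp3:NM_021429.3:intron_0 and Fam20c:NM_030565.6:intron_3 and the repeat copies ID_B1_copy20613 and ID_B1_copy32809 had 121, 260, 523 and 250 counts over the controls and 1, 3, 3 and 3 over the EtOH libraries. The ratios of control to EtOH were 152 (counting interval 26.8 to 6070), 109 (37.0 to 533), 220 (74.7 to 1070) and 105 (35.5 to 513). Control replicate 2 raised 3 of these control means. Without it they were 5.63 ± 2.69 CPM for the Hs1bp3 intron, 20.5 ± 6.06 for ID_B1_copy20613 and 9.44 ± 5.57 for ID_B1_copy32809 (SD, n = 3 each).

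The number of features past the threshold was unsteady, and 437 features shared an adjusted p of 0.0525, 320 of them higher and 117 lower in the EtOH libraries. Without control replicates 1, 2, 3 and 4 the count was 8, 10, 8 and 20, and without EtOH replicates 1, 2, 3 and 4 it was 346, 487, 2332 and 3. At an unadjusted p below 0.05, edgeR gave 1829 higher and 936 lower. DESeq2 gave 1343 higher and 404 lower, and limma voom 416 and 239, with adjusted p. When library size alone set the scale, 1 feature rose and 8 fell, and the median log2 fold change over all features moved from -0.09 to 0.18.

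Nearly all mature miRNAs had lower values in the EtOH libraries. The median log2 fold change of the 228 miRNA features tested was -1.56, with quartiles of -1.92 and -1.04, and 193 of the 196 features with mature names had fitted values below 0. The miRNA median was -1.46, -1.27 and -1.42 with median-of-ratios factors, library size alone and piRNA cluster totals as the scale, where the median of all features was -0.001, 0.18 and 0.15. By the edgeR test 1 miRNA feature rose, mir-196a-1, and 1 fell, miR-669a-5p, from the large miRNA cluster within the Sfmbt2 gene, with 324 ± 109 CPM in controls and 61.7 ± 13.4 in the EtOH libraries (SD, n = 4 each; log2 fold change -2.39, SE 0.40, adjusted p = 0.0384). At an unadjusted p below 0.05, 152 miRNA features were lower and 3 higher. DESeq2 put 117 lower past its adjusted threshold and limma voom 74. Without EtOH replicates 1, 2 and 3 the edgeR count was 8, 68 and 140, and without EtOH replicate 4 or control replicate 1, 2 or 3 it was 1. The next miRNAs by p, miR-743b-3p, miR-499-5p and miR-743a-3p, had log2 fold changes of -2.10, -2.70 and -2.11 with an edgeR adjusted p of 0.0525. Above 0, the next were the precursors mir-7222, mir-468 and mir-7218, at 1.14, 1.31 and 0.81 (adjusted p = 0.155, 0.181 and 0.299).

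**Figure D2:**
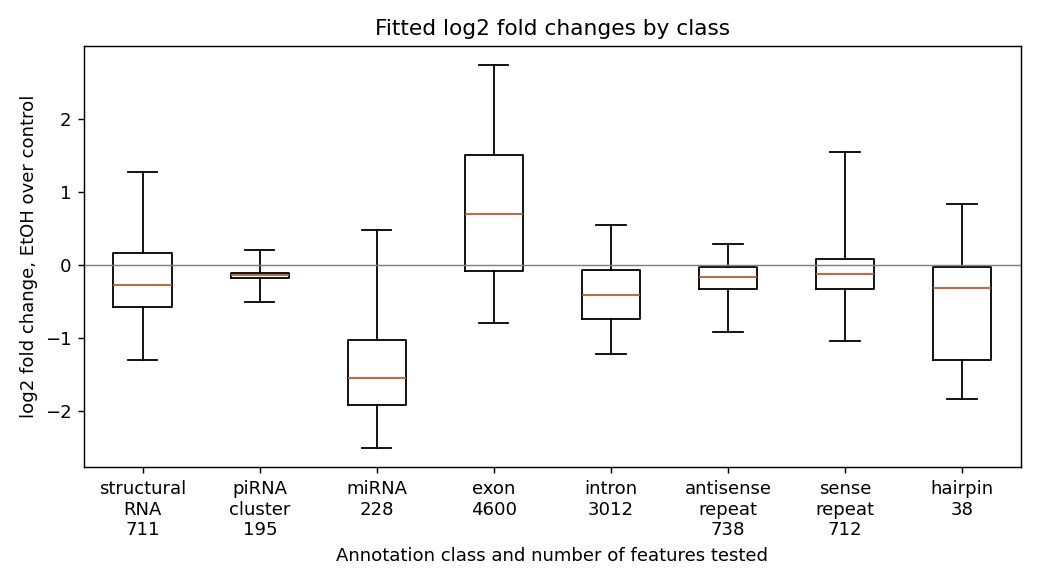
Fitted log2 fold changes, EtOH over control (vertical axis), for the features tested in each annotation class (horizontal axis, with the number tested). Boxes span the quartiles, orange lines are medians and whiskers run from the 5th to the 95th percentile. The miRNA median is -1.56 and the exon median 0.70, and the piRNA cluster median is -0.14, which becomes 0.11 with library size alone.

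The most abundant miRNA, miR-16-5p, had 70300 ± 22500 CPM in controls and 24000 ± 5900 in the EtOH libraries, and miR-191-5p 9060 ± 1940 and 3090 ± 577 (SD, n = 4 each; edgeR adjusted p = 0.0525 for both). miR-143-3p, a smooth muscle miRNA, had 11500 ± 14200 and 2350 ± 977 CPM (adjusted p = 0.0768), with 4510 ± 2690 in controls without control replicate 2 (SD, n = 3). let-7a-5p and let-7c-5p were listed at 0 in control replicate 2 and at 64880 or more and 31924 or more counts in the other controls, so their fitted folds rest on that 0 and are not given here. The count table holds 51 such features, listed at 0 where the other libraries predict 50 or more counts, 35 of them in 1 library and 16 in 2 to 4, and 28 of the 51 are miRNAs.

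Of the fixed miRNA lists, 2 fell as a whole by fry, and both calls were lost with an estimated correlation (adjusted p = 0.348 for each). Their medians lay -0.06 and -0.18 from the median of all miRNA features. The 10 tested members of the miR-17/92, miR-106 and miR-25 clusters, polycistronic miRNAs linked to cell proliferation, had a median of -1.61 (limma fry adjusted p = 0.0224), and none passed the edgeR test over all features while 9 were lower adjusted over the list alone. DESeq2 and limma voom each put 8 of them past the threshold, and 9 had an unadjusted p below 0.05. miR-92a-3p had 2270 ± 158 and 744 ± 229 CPM, and miR-93-5p 2870 ± 736 and 957 ± 218 (SD, n = 4 each). The leukocyte miRNAs (miR-142, miR-223, miR-155 and miR-150) had a median of -1.74 (fry adjusted p = 0.0377), with 3 of 5 lower adjusted over the list alone and 0 over all features by edgeR, 3 by DESeq2, 1 by limma voom and 3 at an unadjusted p below 0.05. miR-223-3p had 25 ± 20.1 and 5.97 ± 1.60 CPM and miR-150-5p 79.2 ± 77.4 and 12.7 ± 6.54 (SD, n = 4 each). Without control replicate 2 their control means were 15 ± 3.16 and 41.7 ± 22.5 CPM (SD, n = 3 each). For miR-150-5p, control replicate 1 lay below EtOH replicate 1. The miR-17/92 call was lost without control replicate 1 or 4 or EtOH replicate 1 (adjusted p = 0.0988, 0.0937 and 0.16), and the leukocyte miRNA call without control replicate 1, 2, 3 or 4 or EtOH replicate 1 (0.0988, 0.0738, 0.0926, 0.103 and 0.172) and without features with isolated zeros (0.104). Scaling to piRNA cluster totals ended both (0.166 and 0.0717).

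The X-linked testis miRNAs, a cluster expressed in male germ cells, had a median of -1.85, and 19 of 21 were lower adjusted over the list alone, as were 17 by DESeq2 and 15 by limma voom over all features, but the list missed the threshold (fry adjusted p = 0.0574), except without EtOH replicate 3 (0.0444). miR-465a-5p had 266 ± 135 and 62.3 ± 15.6 CPM and miR-465c-5p 1050 ± 333 and 291 ± 93.8 (SD, n = 4 each). The let-7 family, the miR-34 and miR-449 family, the miRNAs named in earlier work on paternal stress or ethanol, and the redox and mitochondria-associated miRNAs had medians of -1.54, -1.10, -1.26 and -1.72 (fry adjusted p = 0.073 for each). Adjusted over the list alone, 8 of 11, 3 of 6, 10 of 26 and 7 of 7 of their members were lower. miR-34c-5p, an abundant sperm miRNA, had 6550 ± 1350 and 3280 ± 1350 CPM (SD, n = 4 each; edgeR adjusted p = 0.125), and miR-30c-5p 6080 ± 1340 and 2080 ± 307 (adjusted p = 0.0525). Without EtOH replicate 3 the miR-34 and miR-449 list and the list from earlier work passed (fry adjusted p = 0.0224 for each), and without control replicate 2 the redox list did (0.0417). The miRNAs of red blood cells, smooth muscle and striated muscle had the lowest medians of the miRNA lists, -2.43, -2.80 and -2.48 (fry adjusted p = 0.12, 0.357 and 0.12). Without control replicate 2 the smooth and striated muscle medians were -0.99 and -1.57. Control replicate 3 lay within the range of the EtOH libraries in the sums of both muscle lists and of the red blood cell list. miR-451a, the main red blood cell miRNA, had 386 ± 340 and 47.2 ± 16.2 CPM (SD, n = 4 each), with 61.5 in control replicate 3 and 62.4 in EtOH replicate 3. The epithelial miR-200 family had a median of -0.55, or -0.20 without control replicate 3 (fry adjusted p = 0.559), with miR-200b-3p at 1510 ± 893 and 880 ± 278 CPM (SD, n = 4 each). It includes miR-141-3p, listed at 0 in control replicates 1 and 4 and EtOH replicates 3 and 4. The miR-10 and miR-125, liver and gut, miR-30, miR-29 and miR-183 lists had medians of -0.97, -1.52, -1.01, -1.19 and -0.78 (fry adjusted p = 0.12, 0.12, 0.611, 0.211 and 0.211). Of the 7 tested miR-30 features, 3 had isolated zeros. miR-30a-5p was listed at 0 in control replicates 1 and 4 and EtOH replicate 3. miR-30e-5p was at 0 in control replicate 4, and miR-30e-3p in control replicates 3 and 4. The miR-29 median was -0.77 without EtOH replicate 2.

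Among tRNA-derived features, 1 of 472 fell, a copy of the alanine tRNA (tRNA-Ala-GCY__copy1340), with 18.9 ± 20.8 CPM in controls and 0.266 ± 0.435 in the EtOH libraries (SD, n = 4 each; edgeR adjusted p = 0.0341). Without control replicate 2 its control mean was 8.54 ± 2.86 CPM (SD, n = 3). Without EtOH replicate 2 its EtOH mean was 0.052 ± 0.0901 (SD, n = 3). This copy does not stand for alanine tRNA as a whole. Of 36 alanine features tested, 8 were fitted above 0 and 28 below. Their list sum was 4465 ± 596 CPM in controls and 5322 ± 1080 in the EtOH libraries (SD, n = 4 each). Over all 472 tRNA-derived features, 32 were higher and 15 lower at an unadjusted p below 0.05. Copies with near-identical counts are counted apart here, so these are not separate signals. Aspartate and lysine features made up 13 and 9 of the 32, and serine features 7 of the 15. The count past the threshold was 3, 3 and 21 without EtOH replicates 1, 2 and 3, and 0 without EtOH replicate 4 or control replicate 1 or 3. With copies summed it was also 0. The most abundant tRNA features were copies of glycine tRNA (tRNA-Gly-GGY) that carried near-identical counts, each with 8900 ± 1670 and 8300 ± 5130 CPM (SD, n = 4 each), a difference within the spread between libraries. Aspartate tRNA features had a median log2 fold change of 1.43, and 13 of 18 were higher adjusted over the list alone, but the list did not pass (fry adjusted p = 0.307). Its copies carry near-identical counts, and each of the 4 lowest by p had 1150 ± 128 and 3090 ± 2700 CPM (SD, n = 4 each). Without EtOH replicate 2 their EtOH mean was 1760 ± 631 CPM (SD, n = 3) and the list median 0.61, and EtOH replicate 3, at 1150 CPM, lay within the controls. Of the methionine tRNA features, 2 of 27 were higher adjusted over the list alone, near-copies of which tRNA-Met__copy25 had 10.1 ± 3.71 and 40.8 ± 18 CPM (SD, n = 4 each), while the list did not pass (fry adjusted p = 0.798). The histidine, lysine, serine, proline, tryptophan, asparagine, leucine, glutamate and valine tRNA lists did not pass (fry adjusted p = 0.174, 0.559, 0.12, 0.12, 0.167, 0.317, 0.217, 0.387 and 0.765). The alanine, arginine, cysteine, glutamine, glycine, isoleucine, phenylalanine, threonine and tyrosine lists had fry adjusted p of 0.357, 0.357, 0.495, 0.803, 0.825, 0.484, 0.317, 0.748 and 0.798. For glutamine and valine the median lay above 0 while the test pointed down, and for tyrosine the median lay below 0 while the test pointed up.

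Messenger RNA fragments of genes known from the epididymal epithelium had higher values in the EtOH libraries, and the source of the fragments was not identified. Crisp1, which encodes a secreted protein that coats maturing sperm, had 371 ± 75.7 CPM summed over its exons in controls and 3968 ± 5540 in the EtOH libraries, where the 4 values were 2118, 12220, 548.9 and 979.4. Adam7, another epididymal gene, had 9.22 ± 9.21 and 507 ± 944 CPM, and Cd52, which encodes a surface glycoprotein of leukocytes and of the epididymis, 53.9 ± 9.78 and 1048 ± 1620 (SD, n = 4 each). Without EtOH replicate 2 the EtOH means were 1220 ± 811, 35.2 ± 16.8 and 240 ± 119 CPM for Crisp1, Adam7 and Cd52 (SD, n = 3 each). Without control replicate 1 the Adam7 control mean was 4.8 ± 3.11 CPM (SD, n = 3). The 13 tested exon features of the epididymal list had a median log2 fold change of 3.37, and 12 were higher adjusted over the list alone. Exon features rose in general, with a median of 0.70 over all 4600, of which 1691 were higher at an unadjusted p below 0.05. The 4 lowest by p were all exons of Crisp1. That gene held 371 of the 395 CPM of the list sum in controls and 3968 of 4522 in the EtOH libraries. Exons of the same gene in the same libraries are not independent. None of the 13 features passed the edgeR test over all features, while 9 did by DESeq2, 10 by limma voom and 12 at an unadjusted p below 0.05. The list did not pass (fry adjusted p = 0.12). Without EtOH replicate 2 its median was 1.69, against 0.38 for all exon features, with 11 of 13 features higher adjusted over the list alone. The caput genes Lcn5, Lcn8 and Lcn9 had 0.789, 0.932 and 0.688 CPM in the EtOH libraries and 0.403, 0.46 and 0.115 in controls, at or near the floor.

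Transcripts of late sperm precursors had somewhat lower values, with a list median of -0.53 over 30 features (fry adjusted p = 0.12), and 0 passed by edgeR, 3 were lower at an unadjusted p below 0.05, 2 by DESeq2 and 0 by limma voom. The median was -0.26 with library size alone, -0.23 with piRNA scaling and -0.30 without EtOH replicate 1. Of the 30 features, 26 were fitted below 0 and 4 above. Smcp, a sperm mitochondrial capsule protein, had 160 ± 14.9 and 101 ± 9.15 CPM, Prm1, a protamine that packs sperm DNA, 29.6 ± 5.28 and 17.5 ± 4.93, and Odf1, an outer dense fibre protein, 105.6 ± 5.83 and 84.3 ± 16.6 (SD, n = 4 each). These genes were picked after the values were seen, and the other genes of the list overlapped between the groups. Prm2 had 63.9 ± 14.1 and 52.9 ± 11.1 CPM and Tcp11 23.2 ± 3.11 and 23.3 ± 6.65 (SD, n = 4 each). The 13 mitochondrial protein-coding genes had a median of -0.32 (fry adjusted p = 0.798), which became 0.01 when library size alone set the scale and ran from -0.61 without control replicate 2 to 0 without control replicate 3. By edgeR 0 of them passed, 0 had an unadjusted p below 0.05, and 0 passed by DESeq2 or limma voom. Of the leukocyte transcripts, 2 of 4 features were higher adjusted over the list alone and both belong to Cd52 (list fry adjusted p = 0.484), while Ptprc, the pan-leukocyte CD45 gene, had 0.894 ± 0.514 and 0.673 ± 0.311 CPM and Lyz2 2.01 ± 1.08 and 1.005 ± 0.513 (SD, n = 4 each). Haemoglobin gene Hba-a1 had 5.92 ± 1.79 and 1.63 ± 1.18 CPM (SD, n = 4 each), with 1.07 ± 0.395 in the EtOH libraries without EtOH replicate 4 (SD, n = 3). The Y RNAs, small RNAs bound by the Ro protein, had a median of 1.77, with 4 of 4 higher adjusted over the list alone (fry adjusted p = 0.211), and a median of 0.74 without EtOH replicate 2. The small nucleolar RNAs had a median of -0.77, with 6 of 84 lower adjusted over the list alone (fry adjusted p = 0.196) and a median of -0.43 with library size alone and -1.18 without EtOH replicate 2, among them Snord85 at 1350 ± 341 and 329 ± 201 CPM (SD, n = 4 each). The spliceosomal RNA, 28S ribosomal RNA and piRNA cluster lists had fry adjusted p of 0.904, 0.308 and 0.611. The median of the spliceosomal list was 0.22 although the test pointed down, and it was -0.49 without EtOH replicate 2.

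**Figure D3:**
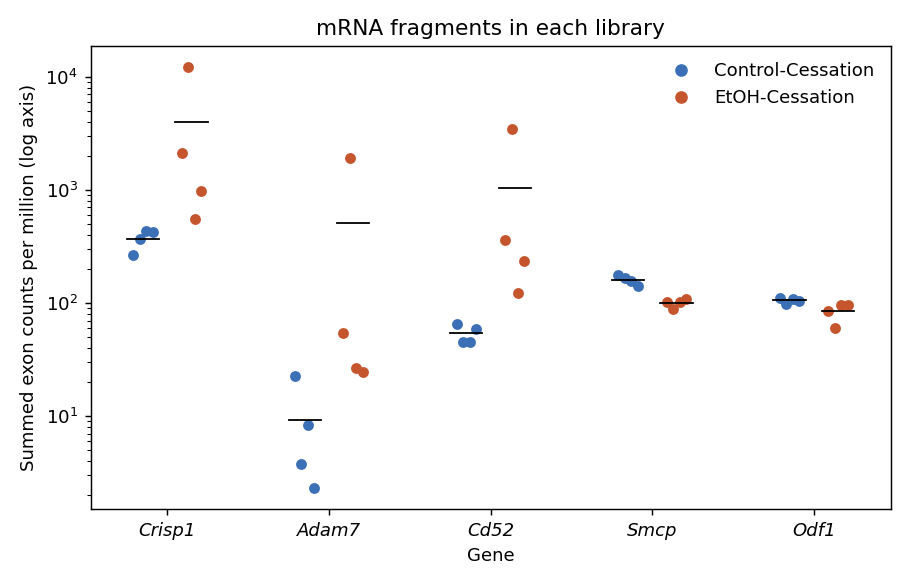
CPM summed over the exons of each gene (vertical axis, log scale) for 5 genes (horizontal axis), with 1 point per library (blue, Control-Cessation; orange, EtOH-Cessation) and a black line at the mean of 4 libraries. Each EtOH library lies above every control for Crisp1, Adam7 and Cd52, and below every control for Smcp and Odf1. With scaled library sizes the groups overlap for the Adam7 exons.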

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

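All tests of explanations in this part were chosen after the results were seen, except the counts over other splits for features, miRNAs, tRNA-derived features and lists. In 168 groups of 4 values, 13 (7.74%) had a library far from the other 3. Chance gives 8.4 at 5% for independent, normally distributed values. Lists and copies here share counts, so the comparison with 8.4 decides little. Of the 13, 6 were EtOH replicate 2. That library had an exon share of 30.5% (others 9.08% to 10.4%), 25000 summed CPM of spliceosomal RNA (4680 to 6230), 14200 of epididymal transcripts (609 to 2210), 3530 of leukocyte transcripts (139 to 383), 1580 of glutamine tRNA (2310 to 2350) and 1080 of tryptophan tRNA (688 to 748). Control replicate 2 had a miRNA share of 27.7% (16.8% to 18.6%), 33400 summed CPM of miR-143 and miR-145 (1650 to 6930), 89.4 CPM of ID_B1_copy20613 (15 to 27) and 0 CPM of let-7a-5p (15900 to 18800). EtOH replicate 3 had 20100 summed CPM of the miRNAs from earlier work (13100 to 13900) and 6.21 CPM of mir-7218 (2.12 to 2.65), and EtOH replicate 1 had 0.156 CPM of the Hs1bp3 intron where the others had 0.

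The lower miRNA share could follow from dilution by exon fragments, but the log2 ratio of miRNA to piRNA cluster counts, which dilution leaves alone, differed by -1.231 (exact permutation p = 0.02857, n = 4 per group), with no overlap between groups. Loss of miRNAs that somatic cells brought to the control libraries would spare germ-line miRNAs, yet the X-linked testis miRNAs had a median log2 fold change of -1.845. Such a loss alone therefore does not account for the fall, but a part in it stays open. The red blood cell, smooth muscle and striated muscle miRNAs had lower medians, -2.43, -2.80 and -2.48. Without control replicate 2 these were -2.60, -0.99 and -1.57, against -1.54 for the X-linked list. Size selection or a library batch that differed between groups cannot be told apart from treatment, since 0 libraries carry a batch label. The identifiers have the form CM in all controls, M in EtOH replicates 1 and 2 and EM in EtOH replicates 3 and 4. These forms may mark batches or cohorts (2572 features passed with the M libraries only and 19 with the EM libraries only). The miRNA median log2 fold change was -1.89 with the M libraries only and -1.31 with the EM libraries only. In the same fits the medians of all features were -0.207 and 0.106. The fall was therefore seen with either form. Neither is the form of the controls, so a batch that differed between groups stays open. A lasting effect of alcohol stays open and was not tested apart from these explanations.

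The higher epididymal transcripts did not rest on EtOH replicate 2 alone, by a list sum that is mostly Crisp1 and uses library totals. The lowest of the other 3 EtOH libraries had 1.33 times the sum of the highest control. With scaled library sizes the 4 Crisp1 exons lowest by p still separated the groups, while the summed Adam7 exons overlapped. Cells of the caput epithelium cannot be told apart. Lcn5, Lcn8, Lcn9, Cst11 and Defb41, chosen after the values were seen and near the floor, summed to at most 0.589% of Crisp1 CPM in an EtOH library. That share depends on the genes chosen, and leaves out Adam7 and Defb42 of the same list. Rnase10, also near the floor, went from 0.683 ± 0.274 to 2.41 ± 0.878 CPM (SD, n = 4 each), with no overlap. Defb42 went from 9.105 ± 5.38 to 31.15 ± 10.8 CPM (SD, n = 4 each), with no overlap, while Gpx5 overlapped between the groups. Epithelial cells of later segments may also be a source. The miR-200 sum did not separate the groups (exact permutation p = 0.571) from a high baseline and with miR-141-3p at 0 in 4 libraries. Of 14 tested general epithelial genes, 10 rose (edgeR adjusted p, exon counts summed by gene), where 1322 of all 6424 exon genes did. That list was written after the values were seen, so it is no independent test of a source. Their median log2 fold change was 2.01, against 0.83 for all exon genes (1.23 against 0.45 without EtOH replicate 2). Without any 1 control 0 passed, but all 14 stayed above 0. Without control replicates 1, 2, 3 and 4 their medians were 1.66, 2.03, 1.81 and 2.07, against 0.65, 0.82, 0.78 and 0.80 for all exon genes. Neither source can be told apart from a change in sperm.

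Loci with at least 1.5 CPM in each library of a group, and under 10% of its lowest value in each library of the other, numbered 7 for the controls and 2 for the EtOH libraries. The 2 were mir-196a-1 and an exon of Prps2. That exon had 75 counts against 0, at least 15.7-fold higher by the exact 95% counting interval, and was not among the features past the threshold. Of the 35 splits of the libraries, 1 gave as many such loci on a side, the real split, and the highest other gave 1. The rule was set after these loci were seen, so this count decides nothing about chance. Lower transcription of the host genes cannot be told apart, since the summed other introns of Trim67, Fam20c and Hs1bp3, with a median log2 ratio of -1.11, held 10 or fewer counts per library. An outside source or a library batch may also have set these loci, and 0 libraries carry a batch label that would test it.

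For the count of 19 features past the threshold, 1 of 35 splits gave as many, the real split, and the highest other gave 1. For miRNAs the real count was 2 and the highest other 1, for tRNA-derived features 1 and 0, and for lists 2 and 0, each with 1 of 35 splits as large. A share of 1 in 35 is the smallest these splits allow. The other splits mix the groups, so a difference between groups adds to the spread within each side and lowers their counts. The share therefore does not exclude chance, and a single tRNA copy against 0 carries little. The list count became 0 with an estimated correlation (adjusted p = 0.348 for both lists), with piRNA scaling and without control replicate 1 or 4 or EtOH replicate 1, and the tRNA-derived count became 0 with median-of-ratios factors, library size alone, piRNA scaling or summed copies and without control replicate 1 or 3 or EtOH replicate 4. The miRNA count became 1, the highest of the other splits, with median-of-ratios factors, library size alone, a mean count of 10, the EM libraries only or miRNAs alone and without control replicate 1, 2 or 3 or EtOH replicate 4, and with piRNA scaling it became 0 and the feature count 1. At an unadjusted p below 0.05 the real split gave 2765 features. The highest other gave 2723, in the split that exchanges control replicate 2 and EtOH replicate 3. That split keeps most libraries of each group together, and another structure of the samples was not tested apart from the groups.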

How the results depend on the processing

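Direction was steadier than the number of calls, and the cause of each change below was not tested unless stated. The main counts were 19 features, 2 miRNAs, 1 tRNA-derived feature and 2 lists. In that order, features, miRNAs and tRNA-derived features numbered 9, 1 and 0 with median-of-ratios factors and with library size alone, 1747, 118 and 22 with DESeq2, 655, 75 and 3 with limma voom, 1642, 32 and 6 with no filter, 11, 1 and 1 at a mean count of 10, 3208, 142 and 52 with total count as a covariate, 19, 1 and 2 with the EM libraries only (EtOH replicates 3 and 4; 12 higher and 7 lower, 8 of them shared with the main 19), and 2572, 103 and 15 with the M libraries only (EtOH replicates 1 and 2). miRNAs fitted alone gave 1 and tRNA-derived features alone 3. Chosen after seeing the data, the fit without isolated zeros gave 700, 81 and 3, scaling to piRNA clusters 1, 0 and 0, an adjusted p of 0.1 gave 1545, 121 and 3 by construction, and summed copies and exons 1556, 89 and 0. Leaving out each library gave 3 to 2332 features, 1 to 140 miRNAs, 0 to 21 tRNA-derived features and 0 to 5 lists. Lists numbered 0 with camera, 1 without isolated zeros and 0 with piRNA scaling. The miRNA and exon shares kept their direction under every alternative run, while their side of the threshold says little, since the smallest exact p, 0.02857, passes the adjustment only if 5 or more classes reach it. Other classes with small differences turned: under centred log ratios antisense repeats (0.009829), introns (0.145) and sense repeats (0.007423), and introns relative to piRNA clusters (0.004979). Leaving out each library gave -0.8755 to 0.1936 points for antisense repeats, -0.3571 to 0.2463 for introns, -3.217 to 3.952 for piRNA clusters and -1.489 to 7.529 for structural RNA. Of 2334 values of named features under alternatives, 57 turned. The glycine tRNA copies, at -0.10, became 0.131 with library size alone, 0.001 with limma voom, 0.001 or 0.002 with no filter, 0.285 with the EM libraries, 0.127 among tRNA features alone, 0.248 with piRNA scaling and -0.527 to 0.136 with a library left out. With limma voom, let-7a-5p, let-7c-5p and miR-30c-2-3p became 1.096, 1.224 and 0.249, of which the let-7 values rest on the 0 in control replicate 2, and the 28S copy410 -0.042 (-0.02 to 0.642 with a library left out). miR-200a-3p became 0.135 with the EM libraries, the 28S copy336 -0.088 with the M libraries and Cd74 0.177 with piRNA scaling. Fitted among miRNAs alone, where values are relative to other miRNAs by construction, let-7c-5p became 0.265, miR-125b-5p 0.051, miR-141-3p 0.719, miR-200a-3p 0.915, miR-200b-3p 0.524, miR-210-3p 0.258, miR-30a-3p 0.408, miR-30b-5p 0.05, miR-30c-2-3p 0.179, miR-34a-5p 0.24, miR-34b-5p 0.168, miR-34c-5p 0.358, miR-429-3p 1.016 and mir-192 0.483, of which let-7c-5p was fitted over a 0 in control replicate 2 and miR-141-3p over 0 in control replicates 1 and 4 and EtOH replicates 3 and 4. The fry direction of lists far from the threshold turned with library size alone for mitochondrial genes (adjusted p = 0.9), spliceosomal RNA (adjusted p = 0.868), piRNA clusters (adjusted p = 0.932), and alanine, glutamine, glycine, isoleucine, methionine and valine tRNA (adjusted p = 0.948, 0.725, 0.802, 0.868, 0.725 and 0.868). With piRNA scaling it turned for glutamine, glycine and valine tRNA (adjusted p = 0.982 each). With a library left out the adjusted p ran from 0.358 to 0.985 for mitochondrial genes, 0.127 to 0.956 for spliceosomal RNA, 0.465 to 0.984 for glutamine, 0.363 to 0.985 for glycine, 0.508 to 0.973 for methionine, 0.341 to 0.956 for tyrosine and 0.343 to 0.985 for valine tRNA, with the direction turned in at least 1 of these. Shares of all reads, unannotated included, could not be run because the table has no such rows. No paired analysis was run because the replicate numbers are in accession order. At this depth and spread, 2% of simulated 2-fold changes were recovered, so most changes of that size would be missed in that setting. The simulation changed 200 of 10234 features, as many up as down. Recovery depends on the share of features changed, which may differ in the data.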

Other observations

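The tests in this part were chosen after the values were seen. When exon counts were summed by gene, 1322 of 6424 genes rose and 24 fell in the EtOH libraries (edgeR quasi-likelihood test, adjusted p below 0.05). Of 76 genes for cytosolic ribosomal proteins tested, 71 rose and 0 fell, with a median log2 fold change of 2.14. These counts rest on every control: without control replicate 1, 2 or 3, 0 genes passed, and without control replicate 4, 1 rose and 1 fell. Without EtOH replicates 1, 2, 3 and 4, 1625, 761, 2392 and 777 genes rose. The ribosomal protein median lay between 1.24, without EtOH replicate 2, and 2.33, without EtOH replicate 1, when each library was left out. Rpl19 had 7.29 ± 1.33 CPM in controls and 48.8 ± 40.6 in the EtOH libraries, and Rps26 9.48 ± 3.50 and 53.0 ± 36.9 (SD, n = 4 each). S100a11, a calcium-binding protein of many somatic cells, had 2.36 ± 0.465 and 17.1 ± 12.6 CPM (adjusted p = 0.0307), and Tjp3, a tight junction protein of epithelia, 1.27 ± 0.588 and 8.16 ± 3.56 (adjusted p = 0.0307). The epithelial keratin Krt8 had 8.97 ± 3.43 and 49.3 ± 45.6 CPM and the adhesion molecule Epcam 8.49 ± 3.08 and 38.9 ± 35.7 (SD, n = 4 each; adjusted p = 0.0307 for both), and the median of 14 such epithelial genes was 1.23 without EtOH replicate 2. Without that library the EtOH means of Rpl19, Rps26, S100a11, Tjp3, Krt8 and Epcam were 29.1 ± 12.1, 35.1 ± 10.9, 11.1 ± 4.05, 6.59 ± 2.07, 26.7 ± 7.32 and 21.1 ± 2.60 CPM (SD, n = 3 each). Against that trend, Rmrp, the RNA of the ribonuclease that processes ribosomal and mitochondrial RNA, fell from 175 ± 44.5 to 39.4 ± 8.51 CPM (SD, n = 4 each; adjusted p = 0.0307). Of 84 small nucleolar RNAs, 14 fell while 0 rose, counts that became 0 and 0 without any 1 control. Their median of -0.87 was then -0.986, -0.846, -0.867 and -0.993 without control replicates 1, 2, 3 and 4. Without EtOH replicates 1, 2, 3 and 4, 10, 50, 22 and 5 small nucleolar RNAs fell, and 1 rose without EtOH replicate 3.

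The FordPrefect DNA repeat, summed over its copies in the sense direction, fell from 1930 ± 490 CPM in controls to 293 ± 179 in the EtOH libraries (SD, n = 4 each; edgeR adjusted p = 0.0307). Among the features at 0 against the other libraries' counts, miR-19b-3p had 0 counts in EtOH replicate 1 and 20157, 23340, 16103, 17997, 5225, 16396 and 12575 in the others, and miR-29a-3p had 0 in EtOH replicate 2 and 5632 or more elsewhere.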
